A study of Mus musculus with 4 samples.

How the data were processed

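Transcripts were counted in 10 µm sections of mouse testis with photo-isolation chemistry, a method in which ultraviolet light uncages blocked DNA ends so that only RNA copied inside the irradiated area is turned into a library. Wild-type mice and mice lacking H3t, a testis histone H3 variant, were each profiled after irradiation of the entire section and after irradiation aimed at Leydig cells, the steroid-producing cells between the seminiferous tubules. Each of the 4 groups had 3 libraries, which gave 12 libraries in all. The wild-type titles carry the word young and the knockout titles carry no age, so the age of the knockout mice is not given in the sources used here. The labels do not say whether the libraries of a group came from separate animals, so p-values measure only the spread between these libraries and may be too small. Each group was 1 library pool, so a pool effect and a group effect cannot be told apart.

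The deposited files hold raw whole-number counts per gene and no normalization by the authors. Per the submitters' processing notes, UMI-tools, Trim Galore, HISAT2 and featureCounts were used with the GRCm38 mouse genome, with no versions given. UMI-tools handles molecular barcodes, and removal of duplicate molecules is inferred from its use, since the notes give no step order. Strand settings are not given in the sources used here, so reads of overlapping and antisense genes cannot be separated. Reads are taken from 3′ ends, so a count is of transcript ends and not of gene length. The table held 28595 genes, of which 2206 had no count in any library. All gene identifiers were found in the GENCODE annotation of the same build, from which positions were taken. Gene names are those deposited with the counts.

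Count shares are in CPM, counts scaled to library size. Library totals ran from 247539 to 566527 counts in entire sections and from 5947 to 54882 in Leydig-targeted libraries. Counting intervals are exact 95% intervals and, like floors, cover counting error only. A fold against a group with no counts was computed against a floor of 3 counts over the group and is given as at least that fold. With 1 to 3 counts in the lower group the ratio of summed CPM is given with its interval.

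Counts were tested with edgeR 4.0.16 and its robust quasi-likelihood test in R 4.3.3, in a fit of all 12 libraries with 1 coefficient per group. Scaling was by the trimmed mean of M values (TMM). Genes were kept by the package's expression filter, with a minimum count of 10, which here means about 66.1 CPM in at least 3 libraries, and 5182 genes were tested. Calls are at a Benjamini-Hochberg adjusted p under 0.05. There were 4 comparisons between groups: knockout against wild type in entire sections and in Leydig-targeted libraries, and Leydig-targeted against entire section in each genotype. The genotype by region interaction was tested in the same fit.

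Before the data were examined, 24 gene lists with 489 entries were fixed, of which 478 were in the table. They cover steroidogenesis, Leydig identity, cholesterol synthesis, the cell cycle, growth and G1 genes, heat shock, endoplasmic reticulum stress, oxidative stress, p53, senescence and apoptosis, immediate early genes, and inflammation and interferon. Others cover mitochondrially encoded and nuclear oxidative phosphorylation genes, spermatogonia, spermatocytes, round and elongating spermatids, Sertoli, peritubular myoid, macrophage, endothelial, stromal, red blood and lymphoid and mast cells. The 11 entries missing from the table, among them Insl3, Tnf and Amh, are not analysed here. Only Kit is in more than 1 list. Lists were tested with camera in limma 3.58.1 on log CPM with a prior count of 2 and a preset correlation of 0.01, and again with an estimated correlation and with fry, which asks whether a list moves one way on balance. No list call held with an estimated correlation.

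The rule for named genes was also fixed before the data were examined. It takes the 10 higher and 10 lower genes with the smallest adjusted p whose libraries did not overlap, leaving out predicted or unnamed gene models, mitochondrial and ribosomal protein genes, then up to 4 members of each list by p, the targeted gene, and 10 interaction genes. After the values were seen, list members named with a value were limited to 2 per list, and in the region comparisons to called members of lists with a camera adjusted p under 0.05. Star, Cyp11a1, Cyp17a1 and Hsd17b3 were added in both genotype comparisons because they carry the steroid pathway the series title names, so these were chosen after their values were seen. A further gene kept under these limits is not reported here.

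Same-numbered entire-section libraries of the 2 genotypes deviated together from their group means, with correlations across genes of 0.243, 0.132 and 0.194. Pairs with different numbers were negative, which is no separate evidence because deviations from a group mean sum to 0. Same-numbered values are over 0.1 in every pair, and these libraries also share barcode numbers, so numbers were taken as pairing the entire sections. The main fit holds no block for this. In the other comparisons the numbers did not pair the libraries. There, wild-type Leydig-targeted replicate 1 with section replicate 2, a pair with different numbers, reached 0.127. Alternatives were DESeq2's size factors, library size alone, TMM over genes not lower in knockout sections, DESeq2 1.42.0, limma-voom, no count filter, a filter of 10 counts in 3 libraries, fits of 6 libraries, a replicate block and leaving out each library. Added after seeing the data were TMM for sparse libraries, leaving out both shallow libraries, scaling to steroidogenesis and Leydig identity counts, and a block over the 6 section libraries alone. Figures were drawn with matplotlib 3.10.9.

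The fit was tested on simulated counts with 200 genes changed in balanced directions among the 5182 genes. Of 50 genes simulated with 8-fold changes it called 98% in the entire-section comparison of genotypes, 44% in the Leydig-targeted comparison, 68% for regions in wild type and 56% for regions in knockouts. With 4-fold changes those shares were 88%, 16%, 40% and 36%. False calls made up 1.85% to 4.76% of calls. With 150 genes raised and 50 lowered, in the same order of comparisons it called 100%, 84%, 94% and 86% of 8-fold changes and 88%, 50%, 52% and 54% of 4-fold changes. All 8-fold and 4-fold changes of that run were rises, so these shares say nothing of large falls. False calls then rose to 23% of calls in the wild-type region comparison and stayed at 1.47% to 4.42% in the others. Every gene was simulated with the same dispersion of 0.0831. Far fewer genes were changed than the 3194 called in the real section comparison. These shares therefore need not hold for the real data.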

Results

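Gene counts were measured in 3 libraries of each of 4 groups of mouse testis section: wild-type and H3t-knockout entire sections, and wild-type and H3t-knockout libraries irradiated at Leydig cells. Entire sections gave 566527, 522652 and 247539 counts in wild type and 475764, 392164 and 321771 in knockouts. Leydig-targeted libraries were far shallower, with 54882, 26853 and 5947 counts in wild type and 53003, 39688 and 15208 in knockouts, so only large differences could be called there. The series design asks how testes with disrupted spermatogenesis, and Leydig cells within them, change in stress, proliferation and testosterone synthesis genes.

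The targeted gene, H3f4 (ENSMUSG00000080152, chromosome 11, 58961812 to 58962222, plus strand), is annotated as an unprocessed pseudogene in GRCm38. It had 1 count in wild-type entire section replicate 1 and 0 counts in the other 11 libraries. Its counts were too low to check any label, and the gene was not tested.

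Spermatocyte and spermatid transcripts were nearly absent from knockout sections, while transcripts of Leydig cells, Sertoli cells and macrophages took a larger share. Spermatocyte and spermatid lists held 5.02% ± 1.32 (SD, n = 3) of counts in wild-type sections and 0.0922% ± 0.0336 (SD, n = 3) in knockout sections. The spermatogonia list held 0.0975% ± 0.00908 (SD, n = 3) and 0.0992% ± 0.00788 (SD, n = 3). Steroidogenesis and Leydig identity lists held 0.627% ± 0.206 (SD, n = 3) and 4.38% ± 0.358 (SD, n = 3). The Sertoli list held 0.679% ± 0.219 (SD, n = 3) and 2.22% ± 0.0700 (SD, n = 3), and the macrophage list 0.0564% ± 0.0134 (SD, n = 3) and 0.278% ± 0.116 (SD, n = 3).

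**Figure D1:**
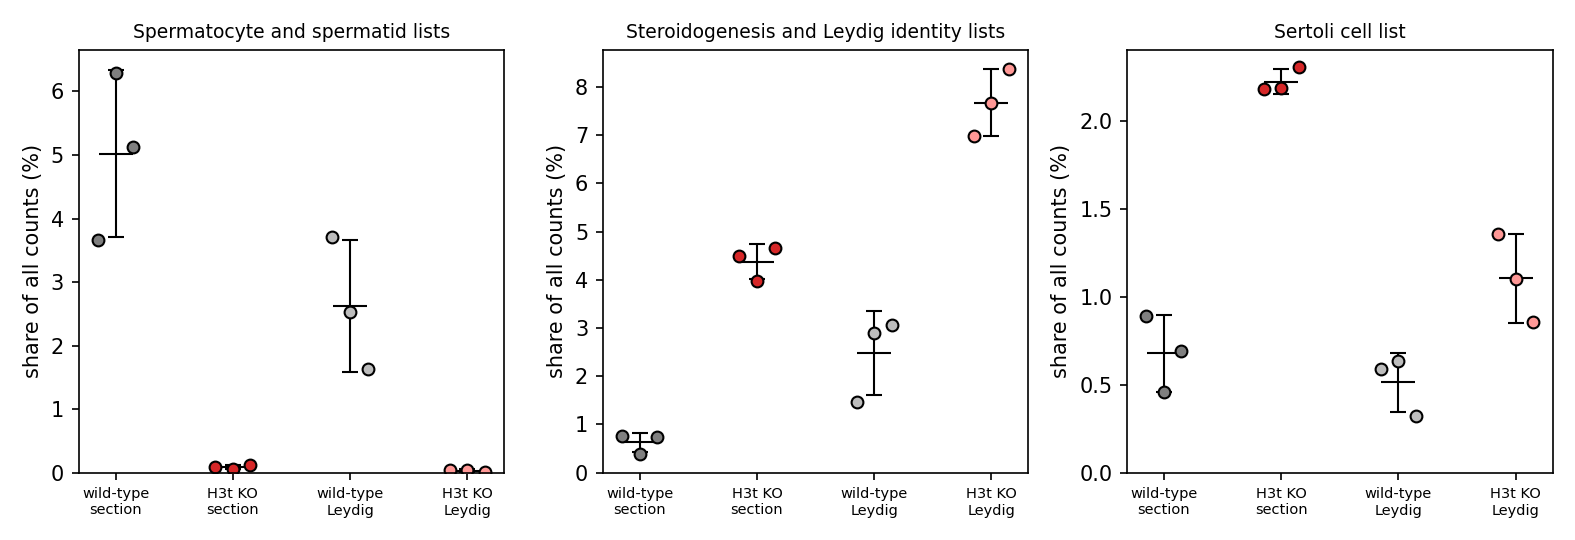
Share of all counts, in percent, taken by 3 sets of fixed gene lists in each of the 12 libraries, with group mean and SD (n = 3, points are libraries). Spermatocyte and spermatid transcripts fell from 5.02% to 0.0922% in sections, and steroidogenesis and Leydig identity transcripts rose from 0.627% to 4.38%.

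In entire sections, 1170 genes were higher and 2024 lower in knockouts among 5182 tested, and 3354 had an unadjusted p under 0.05. Prm1 and Prm2, the protamines that replace histones in sperm, fell by 7.63 ± 0.60 and 7.29 ± 0.58 on the log2 scale. Acrv1 of the acrosome fell by 8.21 ± 0.66 and Gk2, a testis glycerol kinase, by 8.22 ± 0.66, each with adjusted p = 2.72e-32. Rimbp3, needed for the spermatid manchette, fell by 8.64 ± 0.71, Crisp2 of the acrosome by 7.52 ± 0.63, Ccdc60 by 7.89 ± 0.66 and Clec2m by 7.71 ± 0.64. Tssk1, a spermatid kinase, was at least 284-fold lower, with no counts in knockouts, and Tdrd6, a chromatoid body protein, was lower by 1142-fold (204 to 45162 by counting error) on 1 count. All 14 spermatocyte, 10 round spermatid and 16 elongating spermatid genes tested were lower, with camera adjusted p = 6.46e-06, 1.51e-05 and 1.10e-09 (0.189 each with an estimated correlation), and the same counts were adjusted over the list alone. Examples were Ldhc, the germ cell lactate dehydrogenase (-7.23 ± 0.64), and Pgk2, a germ cell glycolytic enzyme (234-fold lower, 64.2 to 1938). Among 8 spermatogonia genes tested, Dmrtb1, Esx1, Id4 and Ddx4 fell and Kit and Uchl1 rose (camera adjusted p = 0.912), 4 lower and 2 higher adjusted over the list alone. Dmrtb1, a regulator of meiotic entry, fell by 5.63 ± 0.60 and Ddx4, a germ cell RNA helicase, by 4.02 ± 0.52.

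Steroid and Leydig genes rose in the same sections. Of 15 steroidogenesis genes tested 11 were higher and Lipe, a lipase, was lower (camera adjusted p = 2.52e-05, or 0.165 with an estimated correlation; 11 higher and 1 lower adjusted over the list alone). Hsd3b6 and Hsd3b1, which make progesterone and androgen precursors, rose by 3.45 ± 0.51 and 2.95 ± 0.49. Hsd17b3, the last step of testosterone synthesis, rose by 3.35 ± 0.56, Cyp11a1, which cuts the cholesterol side chain, by 2.94 ± 0.54, Star, which brings cholesterol into mitochondria, by 2.23 ± 0.48, and Cyp17a1 by 1.59 ± 0.45 (adjusted p = 9.04e-04). These last 4 genes were chosen after values were seen. All 9 Leydig identity genes were higher, with the same p values as for steroidogenesis and 9 adjusted over the list alone. They included Sult1e1, an estrogen sulfotransferase (4.61 ± 0.59), and Ptgds, a prostaglandin synthase (2.83 ± 0.46). Of 14 cholesterol synthesis genes 10 were higher (camera adjusted p = 1.99e-04, or 0.168 with an estimated correlation; 10 higher and 1 lower adjusted over the list alone), among them Sc5d, a sterol desaturase (2.47 ± 0.50). Among genes outside the lists, Wfdc18 had 140 counts in knockouts and none in wild type, at least 35.1-fold higher. Serpina3n, an acute-phase protease inhibitor, was higher by 87.3-fold (15.4 to 3480) on 1 wild-type count. Cdc42ep5 (4.20 ± 0.57), Ass1 of the urea cycle (4.02 ± 0.55), Lrg1 (3.82 ± 0.53), Klk1b27 (3.69 ± 0.53), Serpina3c (3.46 ± 0.53) and Scd1, a fatty acid desaturase (3.46 ± 0.52), also rose.

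Growth and oxidative stress genes rose, while other stress and proliferation lists had no camera adjusted p under 0.05. The 5 lower cell cycle genes of 7 tested, Ccnb2, Aurka, Cenpf, Plk1 and Top2a, had camera adjusted p = 0.0507 (0.0462 with the replicate block, 0.33 with an estimated correlation, and from 0.0343 without wild-type Leydig-targeted replicate 1 to 0.0717 without wild-type section replicate 1), and 5 were lower adjusted over the list alone. Aurka, a mitotic kinase, fell by 4.98 ± 0.56 and Ccnb2, a mitotic cyclin, by 3.92 ± 0.51. Spermatocyte and spermatid transcripts were nearly lost from the same sections, so a fall of cell cycle or stress genes within the remaining cells was not shown. Of 8 growth and G1 genes 7 were higher (camera adjusted p = 0.00338, or 0.165 with an estimated correlation; 7 adjusted over the list alone), among them Kitl, the ligand of Kit (2.30 ± 0.47), and Pdgfra (2.15 ± 0.49). In the oxidative stress list 14 of 21 genes were higher (camera adjusted p = 1.29e-04, or 0.187 with an estimated correlation; 14 adjusted over the list alone), among them the peroxide-removing enzyme Gpx1 (2.72 ± 0.48) and the iron store Fth1 (2.67 ± 0.48). The growth and G1 median was 1.77 (quartiles 1.28 to 2.17) and the oxidative stress median 1.28 (0.33 to 2.24), beside 1.26 (1.05 to 1.55) for the Sertoli list. Quartiles overlapped and no test compared these lists, so neither rise was shown to exceed that of Sertoli genes. Of 13 heat shock genes 4 rose and 5 fell (camera adjusted p = 0.557), 4 and 5 adjusted over the list alone, with Dnajb4 and Hsp90aa1, both chaperone genes, falling by 2.25 ± 0.45 and 2.34 ± 0.47. Of 15 endoplasmic reticulum stress genes Atf4 rose and Herpud1, Creld2 and Asns fell (camera adjusted p = 0.756), 0 and 3 adjusted over the list alone, with Creld2 falling by 2.78 ± 0.47 and Asns, an asparagine synthetase, by 1.61 ± 0.52 (adjusted p = 0.117 without wild-type section replicate 1). For both lists the median and mean were negative while camera pointed up. Of 11 genes of the p53, senescence and apoptosis list 5 rose and 3 fell (camera adjusted p = 0.115), 5 and 3 adjusted over the list alone, with Sesn1, a p53 target, rising by 2.79 ± 0.49 and Mdm2, a p53 ligase, falling by 2.22 ± 0.46. Klf6 rose by 1.95 ± 0.51 and Klf4 fell by 2.15 ± 0.52 among 3 immediate early genes (camera adjusted p = 0.609; 1 and 1 adjusted over the list alone), and the list's median and mean differed in sign.

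Other cell types also rose in share. All 10 macrophage genes were higher (camera adjusted p = 1.53e-04, or 0.189 with an estimated correlation; 10 adjusted over the list alone), among them Cd74 and H2-Eb1 of antigen presentation (3.34 ± 0.52 and 2.99 ± 0.49). All 7 inflammation and interferon genes were higher (camera adjusted p = 9.25e-04, or 0.187 with an estimated correlation; 7 adjusted over the list alone), among them the chemokine Cxcl12 (3.21 ± 0.53) and the iron-binding Lcn2 (2.62 ± 0.46). Of 17 Sertoli genes 14 were higher (camera adjusted p = 2.19e-04, or 0.342 with an estimated correlation; 14 adjusted over the list alone), among them Sox9 (2.47 ± 0.47) and the defensin Defb36 (2.17 ± 0.46). Of 6 peritubular myoid genes Tpm1, Myl9 and Mylk rose (camera adjusted p = 0.0383, or 0.189 with an estimated correlation; 3 adjusted over the list alone), Tpm1 by 1.81 ± 0.48 and Mylk by 1.44 ± 0.45 (adjusted p = 0.0516 without wild-type section replicate 3). Of 13 stromal genes Dcn, Igfbp7, Sparc and Nr2f2 rose and Mfap5 fell (camera adjusted p = 0.0273, or 0.45 with an estimated correlation; 4 and 1 adjusted over the list alone), Nr2f2 by 2.01 ± 0.51, and Mfap5 fell by 4.07 ± 0.55. Of 32 nuclear oxidative phosphorylation genes 7 rose and 3 fell (camera adjusted p = 0.0383, or 0.657 with an estimated correlation; 5 and 2 adjusted over the list alone), among them Ndufa4 (1.74 ± 0.45) and Cox7b (1.84 ± 0.49). None of 10 mitochondrially encoded genes was called by edgeR (camera adjusted p = 0.31), including mt-Atp6 (0.89 ± 0.48, adjusted p = 0.0982) and mt-Nd4 (-0.69 ± 0.43, adjusted p = 0.155), and the list's median and mean differed in sign. Kit, the only mast cell list gene tested, rose by 2.39 ± 0.51 (camera adjusted p = 0.167). Hbb-bs of red blood cells (1.29 ± 0.60, adjusted p = 0.0527; 1 adjusted over the list alone) and the endothelial Ly6c1 (-0.61 ± 0.46, adjusted p = 0.239) were not called over all genes. Scaling set the balance of calls: 36.6% were higher with TMM, 52.2% with library size alone, 19.3% with TMM over genes not lower in knockout sections, and 0.317% when libraries were scaled to steroidogenesis and Leydig identity counts. That last scaling was chosen after seeing the data. Of 59 named called genes, 28 moved by over 1.5-fold when some library was left out, 10 of them without knockout section replicate 3.

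In libraries irradiated at Leydig cells, knockouts again had fewer spermatocyte and spermatid transcripts and more steroid, cholesterol and antioxidant transcripts, with fewer genes called at the lower depth. Steroidogenesis and Leydig identity lists held 7.67% ± 0.694 (SD, n = 3) of counts in knockouts and 2.48% ± 0.873 (SD, n = 3) in wild type, while spermatocyte and spermatid lists held 0.0346% ± 0.0186 (SD, n = 3) and 2.62% ± 1.04 (SD, n = 3). Other measures differed as well. Pseudogenes took 2.23% ± 0.198 (SD, n = 3) in knockouts and 4.08% ± 0.648 (SD, n = 3) in wild type, protein-coding genes 94.4% ± 0.441 (SD, n = 3) and 89.1% ± 0.639 (SD, n = 3), and mitochondrially encoded genes 2.31% ± 0.303 (SD, n = 3) and 5.11% ± 2.99 (SD, n = 3). Wild-type Leydig-targeted replicate 3 lay apart from the other 11 libraries, with the highest TMM factor (2.28), the highest mitochondrially encoded share (8.53%) and the lowest second principal component (-146). In this comparison 391 genes were higher and 1085 lower, and 2010 had an unadjusted p under 0.05. The genes tested passed a filter over all 12 libraries. With the filter and fit on the 6 Leydig-targeted libraries alone, 418 genes were tested, with 90 higher and 83 lower. Kit (chromosome 5, 75574916 to 75656722), a receptor of Leydig and germ cells, was higher by 28.2-fold (7.56 to 237) on 2 wild-type counts. Klk1b24 rose by 3.64 ± 0.70, Mgst1, a glutathione transferase, by 4.08 ± 0.79, Idh1, which makes NADPH, by 3.88 ± 0.76, Aldh1a7 by 4.01 ± 0.80, Spon1 by 3.44 ± 0.69, Serping1, a complement inhibitor, by 3.27 ± 0.66 and Lifr, a cytokine receptor, by 3.40 ± 0.73. Atrx, a chromatin remodeller with 41 counts in knockouts and none in wild type, was at least 9.51-fold higher.

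Of 15 steroidogenesis genes, 7 were higher and Lipe lower (camera adjusted p = 0.00741, or 0.277 with an estimated correlation; 7 and 1 adjusted over the list alone). Cyb5a, which aids the lyase step of androgen synthesis, was higher by 39.0-fold (6.72 to 1567) on 1 wild-type count. Hsd3b1 rose by 2.13 ± 0.49, Cyp17a1 (chromosome 19, 46667165 to 46673172, minus strand) by 1.51 ± 0.45 and Hsd17b3 by 1.85 ± 0.65. Star (0.91 ± 0.55, adjusted p = 0.214) and Cyp11a1 (-0.34 ± 0.84, adjusted p = 0.805) were not called. The direction of Cyp11a1 turned without wild-type Leydig-targeted replicate 2 (0.25) or 3 (0.09). Cyp17a1, Hsd17b3, Star and Cyp11a1 were chosen after values were seen. Of 9 Leydig identity genes Nr5a1, Vcam1, Sult1e1 and Ptgds rose (same camera p values; 4 adjusted over the list alone), Vcam1, an adhesion receptor, by 2.25 ± 0.52 and Sult1e1 by 2.78 ± 0.66. Of 14 cholesterol synthesis genes 8 were higher (camera adjusted p = 1.62e-05, or 0.277 with an estimated correlation; 8 adjusted over the list alone), among them the sterol oxidase Msmo1 (2.18 ± 0.62) and Hmgcs1, which makes HMG-CoA (2.49 ± 0.74). The list's median was 2.23, or 1.74 with genes absent from a group at their bound. In the oxidative stress list 11 of 21 genes were higher (camera adjusted p = 1.50e-05, or 0.277 with an estimated correlation; 11 adjusted over the list alone), among them Prdx1, a peroxiredoxin (2.66 ± 0.65), and Txn1, a thioredoxin absent from wild type (at least 5.57-fold). The fitted oxidative stress median was 1.74, or 0.053 when libraries were scaled to steroidogenesis and Leydig identity counts. Without wild-type Leydig-targeted replicate 1, camera adjusted p was 0.123 for steroidogenesis and 0.0614 for Leydig identity, and adjusted p was 0.142 for Cyp17a1, 0.307 for Hsd17b3, 0.0620 for Msmo1, 0.0562 for Hmgcs1 and 0.0566 for Txn1. Without wild-type replicate 3 it was 0.189 for Cyp17a1, and for Hsd17b3 it was 0.0985 without knockout replicate 3 and 0.0732 without wild-type section replicate 1.

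**Figure D2:**
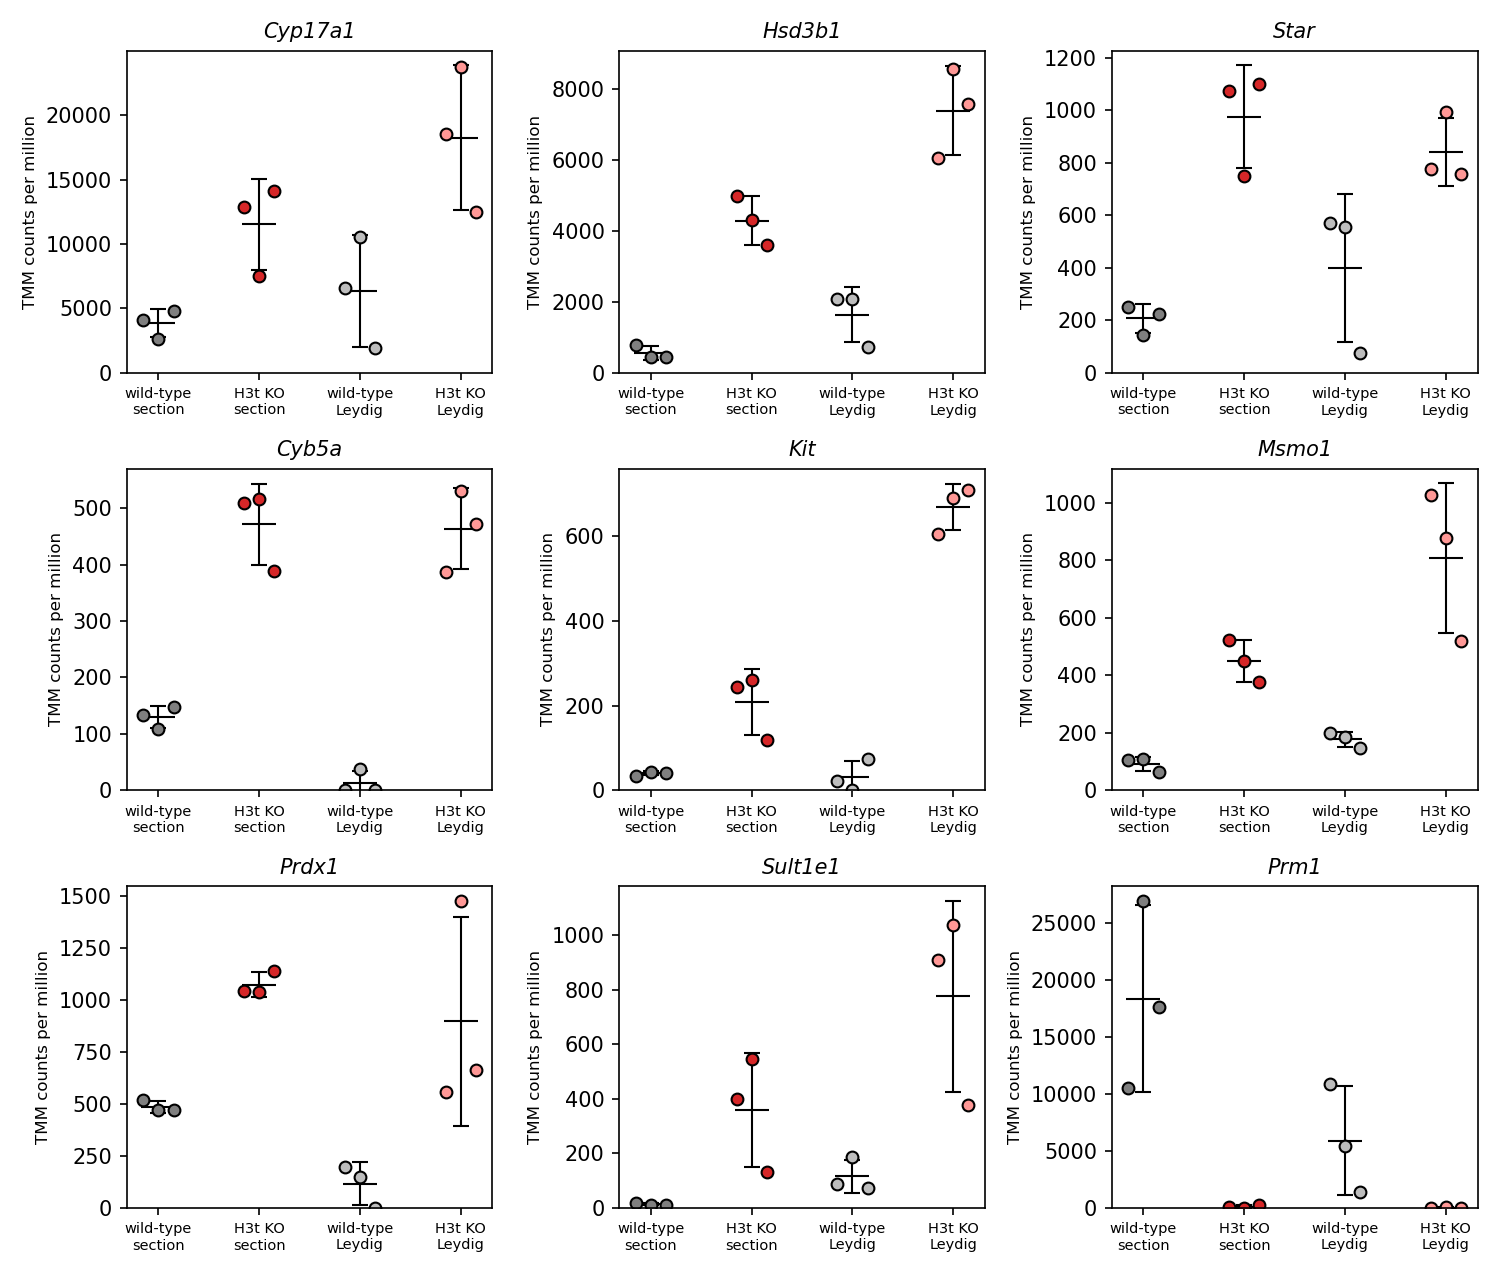
TMM-scaled CPM of 9 genes in each library of the 4 groups, on linear axes from 0, with group mean and SD (n = 3, points are libraries). Hsd3b1 averaged 7387 in knockout and 1629 in wild-type Leydig-targeted libraries, while Star averaged 841 and 399 and was not called. The 9 genes were chosen after values were seen.

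Among lower genes, Prm1 (chromosome 16, 10796326 to 10805839) was 950-fold lower (170 to 37565) on 1 knockout count, and Meig1 408-fold lower (72.6 to 16172). Prm2 fell by 7.35 ± 0.72. Tnp1 and Tnp2, the transition proteins of spermatid chromatin, were at least 143-fold and 56.0-fold lower, Crisp2 at least 105-fold, Ldhc at least 93.9-fold and Spesp1 at least 38.3-fold. Marchf11 was 184-fold lower (32.4 to 7319) and Dkkl1, an acrosome protein, 148-fold lower (26.0 to 5901), each on 1 knockout count. Of 14 spermatocyte genes 12 fell, with 13 adjusted over the list alone (camera adjusted p = 6.75e-06), including Piwil1, a piRNA protein, at least 19.2-fold lower. All 10 round spermatid genes fell, with 10 adjusted over the list alone (camera adjusted p = 0.00147), including Acrv1 (70.4-fold lower, 12.1 to 2836) and the acrosomal protease Acr (at least 15.3-fold). Of 16 elongating spermatid genes 15 fell, with 16 adjusted over the list alone (camera adjusted p = 1.84e-08). With an estimated correlation these p values were 0.277, 0.374 and 0.277. Of 8 spermatogonia genes Kit rose and Dmrtb1 and Ddx4 fell (camera adjusted p = 0.84; 1 and 2 adjusted over the list alone), Ddx4 by 15.3-fold (4.79 to 78.2) on 3 knockout counts, and the median and mean differed in sign.

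Among proliferation and stress lists, 4 of 7 cell cycle genes, Ccnb2, Aurka, Plk1 and Top2a, fell (camera adjusted p = 0.0253, or 0.277 with an estimated correlation; 4 adjusted over the list alone), Ccnb2 and Plk1 being at least 7.66-fold and 3.83-fold lower. The cell cycle median was -5.78, or -1.94 with absent genes at their bound. This list held 0.153% of counts in wild-type and 0.0336% in knockout Leydig-targeted libraries, against 0.158% in wild-type sections. Wild-type Leydig-targeted libraries also held spermatocyte and spermatid transcripts, so a fall of cell cycle genes within Leydig cells was not shown. No growth and G1 gene of 8 was called (camera adjusted p = 0.0369, or 0.277 with an estimated correlation; 0 adjusted over the list alone); Ptch1 was higher by 5.92-fold (1.40 to 52.8, adjusted p = 0.0640) and Igf1r by 5.10-fold (1.53 to 26.6, adjusted p = 0.0757). Hspe1 rose by 2.27 ± 0.80 and Hsp90aa1 and Hspa4 fell among 13 heat shock genes, Hsp90aa1 by 3.52 ± 0.71 (camera adjusted p = 0.827; 1 and 1 adjusted over the list alone), and the median was negative while camera pointed up. Among 15 endoplasmic reticulum stress genes Sel1l rose by 2.11 ± 0.73 and Creld2 fell by 3.49 ± 0.85, as did Asns (camera adjusted p = 0.586; 1 and 2 adjusted over the list alone), and the median and mean differed in sign. Trp53inp1 rose 6.61-fold (1.60 to 58.6) of 11 p53 list genes (camera adjusted p = 0.407; 0 adjusted over the list alone), while Casp8 had 4 counts in knockouts and none in wild type (adjusted p = 0.178). Jund rose by 2.66 ± 0.75 and Klf4 was at least 2.39-fold lower among 3 immediate early genes (camera adjusted p = 0.599; 1 and 1 adjusted over the list alone). Without wild-type Leydig-targeted replicate 1, adjusted p was 0.0611 for Ccnb2, 1 for Plk1, 0.134 for Hspe1, 0.284 for Sel1l, 0.1495 for Creld2, 0.299 for Trp53inp1, 0.0996 for Jund and 0.308 for Klf4. Other single libraries also ended calls. Without knockout Leydig-targeted replicate 1 adjusted p was 0.0608 for Plk1, 0.0711 for Jund and 0.131 for Klf4, and Igf1r was at -1.13. Without knockout Leydig-targeted replicate 2 it was 0.0852 for Sel1l and 0.104 for Klf4, and without replicate 3 it was 0.111 for Hspe1. Without wild-type Leydig-targeted replicate 2 it was 0.0843 for Hspe1, and without wild-type section replicate 1 it was 0.0549 for Hspe1 and 0.0539 for Sel1l. Klf4 had 0.0621 and 0.0531 without wild-type section replicates 2 and 3. Trp53inp1 lost its call without any library but knockout Leydig-targeted replicate 2 and wild-type section replicate 2, with adjusted p from 0.0524 to 0.377.

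Among other cell types, 3 of 10 macrophage genes rose, H2-Aa, H2-Eb1 and Cd74 (camera adjusted p = 0.00473, or 0.277 with an estimated correlation; 5 adjusted over the list alone); H2-Aa was at least 8.35-fold higher and Cd74 31.3-fold (5.34 to 1264). Cxcl12 (12.3-fold, 3.99 to 61.5), Lcn2 (1.77 ± 0.45) and B2m rose of 7 inflammation and interferon genes (camera adjusted p = 0.0237, or 0.277 with an estimated correlation; 3 adjusted over the list alone). Of 17 Sertoli genes Defb19 rose by 2.001 ± 0.57 and Clu was 1.08 ± 0.47 (adjusted p = 0.0688), with camera adjusted p = 0.0660 and 1 adjusted over the list alone. Sparc (1.40 ± 0.48), Gsn (6.96-fold, 2.17 to 35.6) and Igfbp7 rose of 13 stromal genes (camera adjusted p = 0.0374, or 0.573 with an estimated correlation; 3 adjusted over the list alone). Myh11, smooth muscle myosin, was 15.1-fold lower (3.69 to 133) of 6 peritubular genes, with Tpm1 at 1.52 ± 0.93 (adjusted p = 0.218; camera adjusted p = 0.599; 1 adjusted over the list alone), and the list's median and mean differed in sign. Atp5g3 (1.92 ± 0.59), Cox7b (2.34 ± 0.74) and Atp5o rose of 32 nuclear oxidative phosphorylation genes (camera adjusted p = 0.0113, or 0.651 with an estimated correlation; 2 adjusted over the list alone). Of 10 mitochondrially encoded genes mt-Nd4 fell by 1.16 ± 0.44. The complex I gene mt-Nd2 was at -1.17 ± 0.49 (adjusted p = 0.0567; camera adjusted p = 0.362; 0 adjusted over the list alone). Kit was the only mast cell list gene tested (camera adjusted p = 0.0549; 1 adjusted over the list alone), Hbb-bs was at -0.69 ± 0.998 (adjusted p = 0.645), and endothelial Ly6c1 had 3 counts in knockouts and none in wild type (adjusted p = 0.247). Without wild-type Leydig-targeted replicate 1, adjusted p was 0.0585 for Cxcl12, 0.0857 for Lcn2, 0.195 for Sparc, 0.139 for Gsn, 0.0934 for Cox7b and 0.0545 for mt-Nd4. Without knockout replicate 1 it was 0.149 for Cd74, 0.254 for H2-Aa, 0.0723 for Sparc, 0.166 for Gsn and 0.0639 for mt-Nd4, and Hbb-bs was at 0.16. Without wild-type replicate 3 it was 0.174 for Cd74, 0.216 for H2-Aa, 0.207 for Sparc and 0.0552 for Gsn. Without knockout replicate 3 it was 0.140 for Sparc and 0.0525 for Cox7b. For mt-Nd4 it was 0.126 without knockout replicate 2 and 0.0538 without wild-type replicate 2, and for Sparc 0.0596 without wild-type section replicate 1. Of 53 named called genes, 35 moved by over 1.5-fold when some library was left out, 19 of them without wild-type Leydig-targeted replicate 1. Counts of calls moved too: 69 higher and 523 lower without wild-type Leydig-targeted replicate 1, 253 higher without knockout replicate 3, 228 higher without wild-type replicate 3 and 237 higher without wild-type section replicate 1. Of calls, 26.5% were higher with TMM and 1.28% when libraries were scaled to steroidogenesis and Leydig identity counts.

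**Figure D3:**
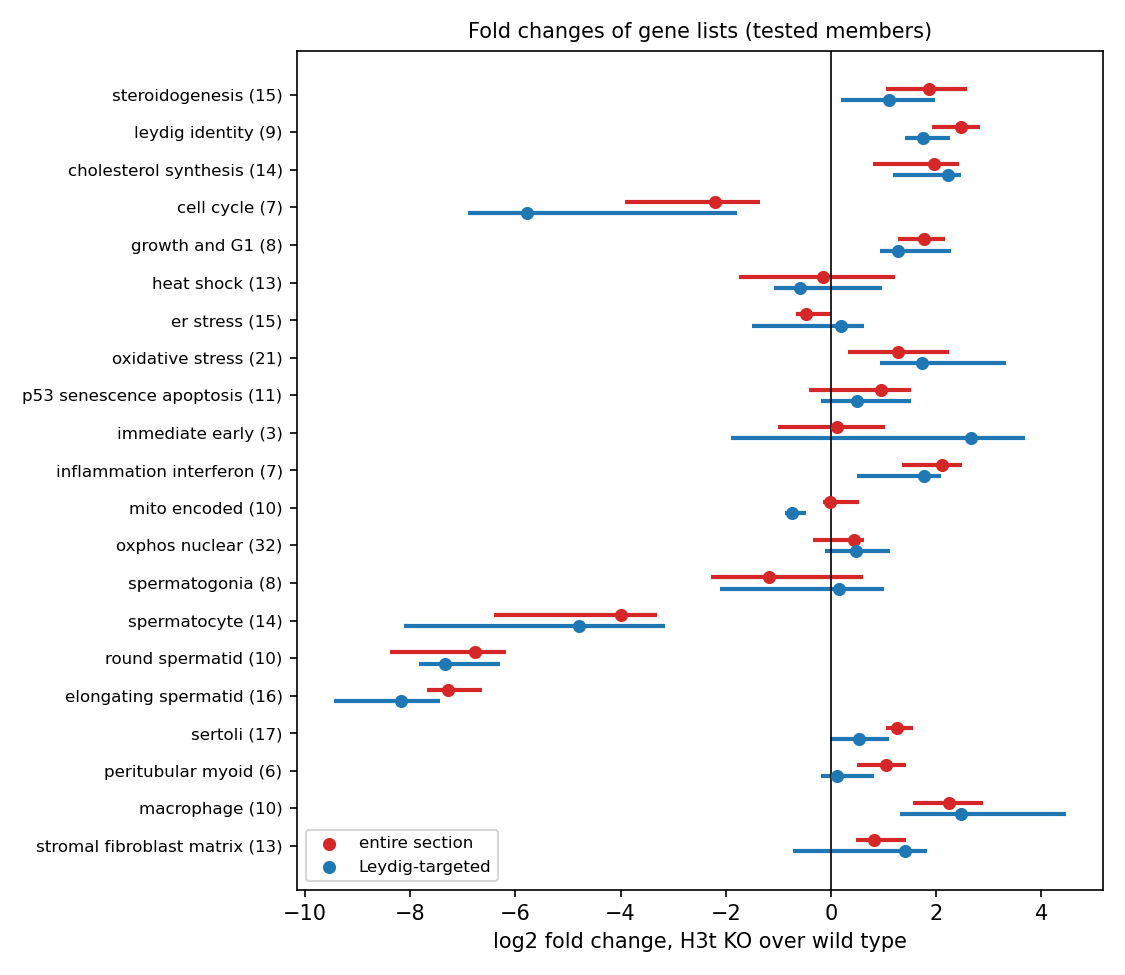
Median log2 fold change of each fixed list, knockout over wild type, in entire sections and in Leydig-targeted libraries, with bars from the lower to the upper quartile and the number of tested genes in parentheses. Medians are of fitted values, which are no bound for genes at 0 counts. With such genes at their bound, Leydig-targeted medians were -2.68 in place of -7.35 for round spermatids, -4.52 in place of -8.17 for elongating spermatids and -3.11 in place of -4.78 for spermatocytes. Spermatid lists lie below 0 in both regions, while steroidogenesis, Leydig identity, cholesterol and macrophage medians lie above 0.

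Calls of the genotype comparisons overlapped across regions. Of 391 genes higher in Leydig-targeted libraries 288 were also higher in entire sections, against 88.3 for independent lists, and of 1085 lower genes 1025 were also lower, against 424. Only 4 and 3 genes were called in opposite directions. Fold changes correlated across genes with Pearson's r of 0.82; genes are not independent replicates, and the comparisons share no library.

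In wild type, steroidogenesis and Leydig identity lists together took a larger share of counts in Leydig-targeted libraries than in entire sections. That share was 2.48% ± 0.873 (SD, n = 3) against 0.627% ± 0.206 (SD, n = 3) in entire sections, and the spermatocyte and spermatid share 2.62% ± 1.04 (SD, n = 3) against 5.02% ± 1.32 (SD, n = 3). The spermatocyte list by itself was not lower, at 0.575% ± 0.144 (SD, n = 3) against 0.552% ± 0.0423 (SD, n = 3). Mean shares were 0.207% against 0.532% for round and 1.84% against 3.94% for elongating spermatids. Pseudogenes took 4.08% ± 0.648 (SD, n = 3) of counts against 1.47% ± 0.0133 (SD, n = 3), and protein-coding genes 89.1% ± 0.639 (SD, n = 3) against 92.5% ± 0.409 (SD, n = 3). In this comparison 167 genes were higher and 642 lower. Ces1d, a carboxylesterase, rose by 4.40 ± 0.62, B3gnt3 by 5.34 ± 0.73, the nuclear noncoding RNAs Neat1 and Meg3 by 3.42 ± 0.51 and 3.37 ± 0.57, Aox1, an aldehyde oxidase, by 3.61 ± 0.60 and Pkdcc by 4.29 ± 0.66. Slx1b, a nuclease subunit, rose by 4.46 ± 0.70, Fbxl18 by 3.65 ± 0.57, Speer4e by 5.31 ± 0.85 and Qpct by 3.88 ± 0.71. Pcsk4, a sperm protease, was 50.8-fold lower (17.3 to 247) on 3 counts, Slc25a39, a mitochondrial carrier, fell by 3.91 ± 0.61, Mt1, a metallothionein, by 3.35 ± 0.53, Isyna1, which makes inositol phosphate, by 3.07 ± 0.55 and Acrv1 by 2.91 ± 0.53. Gps2 was at least 12.1-fold lower, Kpnb1 26.7-fold (7.36 to 221), Srp14 28.2-fold (7.77 to 233) and Csnka2ip 24.3-fold (6.69 to 201), and Tex22 fell by 3.77 ± 0.67. Of 15 steroidogenesis genes 6 rose and Cyb5a fell (camera adjusted p = 7.16e-07, or 0.118 with an estimated correlation; 6 and 1 adjusted over the list alone), Hsd17b3 by 2.89 ± 0.80 and Fdxr by 3.11 ± 0.85 (adjusted p = 0.161 without wild-type Leydig-targeted replicate 1). Vcam1, Prlr, Sult1e1 and Ptgds rose of 9 Leydig identity genes (camera adjusted p = 1.46e-04, or 0.296 with an estimated correlation; 4 adjusted over the list alone), Prlr, the prolactin receptor, by 2.49 ± 0.55 and Ptgds by 1.59 ± 0.45 (adjusted p = 0.0694 without wild-type Leydig-targeted replicate 2). Of 14 cholesterol synthesis genes Fdft1 rose by 1.90 ± 0.66 (camera adjusted p = 0.00768, or 0.456 with an estimated correlation; 0 adjusted over the list alone), with adjusted p = 0.810 without wild-type Leydig-targeted replicate 1 and 0.104 without wild-type section replicate 3. Of 16 elongating spermatid genes 10 fell (camera adjusted p = 0.264), with 1 higher and 11 lower adjusted over the list alone. Of 10 round spermatid genes 4 fell (camera adjusted p = 0.182; 5 adjusted over the list alone). Of 21 oxidative stress genes 6 fell (camera adjusted p = 0.298; 7 adjusted over the list alone). Both mt-Atp6 (2.88 ± 0.59) and mt-Co2 (2.42 ± 0.53) rose of 10 mitochondrially encoded genes (camera adjusted p = 0.00768, or 0.818 with an estimated correlation; 2 and 1 adjusted over the list alone), a list with a negative median and a positive mean. All 25-base words of the copies Gm10925 and Gm28661 were also in mt-Atp6 and mt-Co2, 100% in each, so counts of these genes are uncertain. No other list had a camera adjusted p under 0.05. Counts rested on single libraries: 105 higher without wild-type Leydig-targeted replicate 2, and 234, 358 and 240 lower without its replicates 1, 2 and 3, 350 lower without knockout Leydig-targeted replicate 3 and 247 lower without wild-type section replicate 1. Of 45 named called genes, 34 moved by over 1.5-fold when some library was left out, 24 of them without wild-type Leydig-targeted replicate 1. The share of higher calls was 20.6% with TMM, 57.0% with library size alone, 35.3% with TMM for sparse libraries and 2.22% with Leydig scaling.

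In knockouts, Leydig-targeted libraries had more cholesterol synthesis transcripts and fewer Sertoli transcripts than entire sections, with 99 genes higher and 183 lower. The Sertoli share was 1.10% ± 0.252 (SD, n = 3) against 2.22% ± 0.0700 (SD, n = 3), and the steroidogenesis and Leydig identity share 7.67% ± 0.694 (SD, n = 3) against 4.38% ± 0.358 (SD, n = 3). Fdft1, squalene synthase, rose by 3.50 ± 0.59, Gstm3 by 4.23 ± 0.75, Rnf130 by 3.26 ± 0.58, Ces1d by 2.63 ± 0.49, Pkdcc by 2.41 ± 0.48, Slc25a22, a glutamate carrier, by 3.68 ± 0.76, Prex2 by 3.31 ± 0.73, Mir703 by 3.04 ± 0.52 and Rasd1 by 2.39 ± 0.54. Echdc3 rose by 3.24 ± 0.74 (adjusted p = 0.0612 without knockout Leydig-targeted replicate 1). Marcksl1 fell by 3.01 ± 0.57, Cst9, a Sertoli cystatin, by 2.36 ± 0.53, Wipf3 by 2.64 ± 0.58 and Ssh1 by 2.86 ± 0.64. Cadm1, an adhesion protein, fell by 2.79 ± 0.62 (adjusted p = 0.0536 without knockout Leydig-targeted replicate 2). Adgrg1 was at least 7.44-fold lower, Tmem9 at least 6.57-fold, Clstn1 at least 5.85-fold, Tnik 16.9-fold (4.64 to 140) and Vwa1 13.1-fold (4.44 to 63.7). Of 14 cholesterol synthesis genes 3 rose, among them Fdft1 and Fdps (camera adjusted p = 4.61e-07, or 0.135 with an estimated correlation; 3 adjusted over the list alone). Fdps, a prenyl synthase, rose by 2.44 ± 0.57 (adjusted p = 0.264 without knockout Leydig-targeted replicate 1). Fdx1 and Fdxr, which bring electrons to steroid enzymes, rose by 1.73 ± 0.48 and 1.78 ± 0.56 of 15 steroidogenesis genes (camera adjusted p = 0.00283, or 0.442 with an estimated correlation; 3 adjusted over the list alone). Of 17 Sertoli genes Aard, Cst12, Cst9, Sox9 and Cldn11 fell (camera adjusted p = 1.47e-04, or 0.841 with an estimated correlation; 13 adjusted over the list alone), Cst12 by 2.14 ± 0.53 (adjusted p = 0.0633 without knockout Leydig-targeted replicate 2). The call of Fdx1 ended without knockout Leydig-targeted replicate 1 (adjusted p = 0.0664) and without knockout section replicates 1, 2 and 3 (0.0750, 0.0698 and 0.0722). Fdxr lost its call without knockout Leydig-targeted replicate 2 (0.409), knockout section replicates 1 and 3 (0.154 and 0.105), wild-type Leydig-targeted replicates 1 and 3 (0.0520 and 0.0505) and wild-type section replicates 1 and 3 (0.0672 and 0.0583). No Leydig identity gene was called over all genes by edgeR (camera adjusted p = 0.0893), with 3 adjusted over the list alone, and no other list had a camera adjusted p under 0.05. Of genes higher and lower in wild type, 37 and 55 were also higher and lower here, against 3.19 and 22.7 for independent lists. Counts rested on single libraries: 60 and 56 higher and 82 and 63 lower without knockout Leydig-targeted replicates 1 and 2, and 276 lower without its replicate 3. There were 44 and 48 higher and 75 and 80 lower without knockout section replicates 1 and 3. Lower genes numbered 462, 489 and 371 without wild-type Leydig-targeted replicates 1 and 3 and wild-type section replicate 1. Among 36 named called genes, 12 moved by over 1.5-fold when some library was left out, 9 of them without knockout Leydig-targeted replicate 1. The share of higher calls was 35.1% with TMM, 52.6% with library size alone, 49.3% with TMM over genes not lower in knockout sections, 16.6% with TMM for sparse libraries and 6.19% with Leydig scaling.

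The interaction, which asks whether the genotype difference differs between regions, called 17 genes, 10 higher and 7 lower, with 530 at an unadjusted p under 0.05. These directions depended on the setting, with 14 higher and 47 lower for library size alone and 6 and 32 for TMM for sparse libraries. TMM over genes not lower in knockout sections gave 30 and 6, limma-voom 497 and 58 and the replicate block 4 and 5. No member of the steroidogenesis or Leydig identity list was called by edgeR (camera adjusted p = 0.0661 for both), so the genotype difference of those lists was not shown to differ between regions; 1 steroidogenesis gene was lower adjusted over the list alone. Sesn1 had 64, 98 and 59 counts in knockout sections and 14, 11 and 0 in wild-type sections. Leydig-targeted counts were 6, 4 and 0 in knockouts and 12, 5 and 0 in wild type (interaction -4.03 ± 0.90, adjusted p = 0.00635, or 0.0900 without wild-type Leydig-targeted replicate 1 and 0.0750 without wild-type section replicate 3). The count of calls was 41, 11 and 78 without wild-type Leydig-targeted replicates 1, 2 and 3, 49 without knockout Leydig-targeted replicate 3, 7 and 8 without knockout section replicates 1 and 2, and 35 and 8 without wild-type section replicates 1 and 3. Of 10 named interaction genes, 9 moved by over 1.5-fold when some library was left out, 5 of them without wild-type Leydig-targeted replicate 3.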

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

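The tests of explanations and of other splits in this part were all chosen only after the results were seen, while the interaction itself was planned. The genotype difference differed between entire sections and Leydig-targeted libraries for 17 genes, by the interaction in edgeR, and values are log2 with SE. Fitted values of genes with groups at or near 0 counts are no bound, so counts are given beside them. Sesn1, a p53 target, was at -4.03 ± 0.90. B3gnt3, a glycosyltransferase, was at -5.25 ± 1.004 (adjusted p = 2.20e-04), with 6 counts in wild-type sections and 26 in wild-type Leydig-targeted libraries. Cetn4, a centrin, was at 4.18 ± 0.99 (adjusted p = 0.0152), or 0.0958 and 0.156 without knockout Leydig-targeted replicates 1 and 2 and 0.0890 and 0.0812 without knockout section replicates 1 and 2. Mea1, expressed in male germ cells, was at 5.54 ± 1.34 (adjusted p = 0.0195), or 0.699 without knockout Leydig-targeted replicate 2, 0.0544 and 0.0888 without knockout section replicates 1 and 2 and 0.0650 without wild-type Leydig-targeted replicate 2. With the replicate block 9 genes had an interaction, and Mea1 lost its call. Tmem106c was at 9.14 ± 2.06 (adjusted p = 0.00679, or 0.146 without wild-type Leydig-targeted replicate 1) and Rsl24d1, a ribosome assembly gene, at 8.86 ± 2.11 (adjusted p = 0.0154), both with 0 counts in wild-type Leydig-targeted libraries. For Rsl24d1 it was 0.260 without knockout Leydig-targeted replicate 1, 0.0544 without knockout section replicate 1, 0.188 and 0.0650 without wild-type Leydig-targeted replicates 1 and 2 and 0.0508 and 0.0523 without wild-type section replicates 1 and 3. Gm14128 was at 10.37 ± 1.68 (adjusted p = 1.67e-06) with 149 counts in wild-type sections and 0 in knockout sections, and adjusted p was 1.0 without knockout Leydig-targeted replicate 1, which held its 8 counts there. Gm10721 was at -5.61 ± 1.20 (adjusted p = 0.00305) and Gm13341 at -3.76 ± 0.69 (adjusted p = 9.02e-05), with 45 and 541 counts in wild-type Leydig-targeted libraries. Of the 25-base words of Gm13341 54.0% were also in mt-Co2, so its counts may include mitochondrial reads. The median interaction of mitochondrially encoded genes was -0.71 (camera adjusted p = 0.0175) and that of round spermatid genes 0.67 (camera adjusted p = 0.0452), each with adjusted p = 0.924 with an estimated correlation.

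Gm29216, an unprocessed pseudogene on chromosome 1 (24615706 to 24616197, minus strand), had an interaction of -10.94 ± 0.83 (adjusted p = 3.87e-36). It had 3762 counts in knockout sections and 657 in wild-type Leydig-targeted libraries, against 57 in wild-type sections and 22 in knockout Leydig-targeted libraries. Of its 25-base words 97.2% were also in mt-Co1, so reads of the mitochondrial gene may be counted in the pseudogene. Its ratio to mt-Co1 was at least 5.66 in every library of the high groups and at most 0.474 in the low groups. A mitochondrial sequence variant and a library pool effect cannot be told apart, because each group is 1 pool and maternal lines are not given.

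Other splits of the libraries were fitted for each count of calls. The 10 splits of 6 libraries, the real one included, are too few for a share under 0.05. Every other split mixes the groups compared, so their real difference adds to the spread. Few calls in other splits are therefore no support for the real counts. For knockout against wild type in Leydig-targeted libraries, 2 splits gave at least the real 391 higher genes in either direction and 1 gave the real 1085 lower genes. Either direction was taken because a split and its mirror exchange higher and lower genes. The highest other, 537 lower genes beside 45 higher, was the split that exchanged the shallowest library of each genotype. In entire sections 1 split each gave the real 1170 higher and 2024 lower genes, and the highest other was 0, also among splits that part as many pairs. The region comparisons had 1 split each with the real 167 higher and 642 lower genes in wild type (highest other 0) and the real 99 and 183 in knockouts (highest other 1). For the interaction 9 of 100 permutations of genotype within region gave at least the real 17 genes, the real one included, and the highest other was 2741. The 8 others all kept the genotypes of a region together, which leaves the genotype difference of that region in the interaction. The 80 that mixed genotypes in both regions called 0 genes by edgeR. These permutations therefore cannot say whether chance gives 17 genes.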

How the results depend on the processing

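TMM for sparse libraries, both shallow libraries left out, scaling to steroidogenesis and Leydig identity counts, and the block over 6 section libraries were chosen only after results were seen. Of 217 named results 203 were called, of which 96 kept the call in every setting and 107 lost it in at least 1. Over 5254 comparisons, 4820 had the same direction and side of the threshold, 359 lost and 50 gained a call and 25 turned direction. Leaving out a library kept the 5182 genes, a choice made after 2261 to 8306 genes passed a repeated filter; with it, total calls ran from 588 to 1949 (knockout against wild type, Leydig-targeted), 1384 to 5180 (entire sections), 267 to 1419 (regions, wild type), 85 to 949 (regions, knockout) and 6 to 116 (interaction). The cause of changes was not tested where none is named, and depth limits the Leydig-targeted calls.

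With DESeq2's size factors 160 genes were higher between regions in knockouts. With library size alone 1861 were higher in knockout sections, 320 higher and 241 lower between regions in wild type, 195 higher in knockouts, and 61 had an interaction. With TMM over genes not lower in knockout sections 251 and 595 were higher in knockout Leydig-targeted libraries and sections, 36 had an interaction and the section cell cycle list had adjusted p = 0.0494. The Wald test of DESeq2 gave 180 higher between regions in knockouts and 72 interactions. Limma-voom gave 237 higher in Leydig-targeted knockouts, 623 higher and 399 lower between regions in knockouts and 555 interactions, and put Cyp11a1 at 0.21 in Leydig-targeted libraries. Without a filter, with more genes tested, 437 were lower in Leydig-targeted knockouts, 2416 higher and 4639 lower in knockout sections, 1443 lower between regions in wild type, 54 higher in knockouts and 7 had an interaction, with Cyp11a1 at 0.27. The filter of 10 counts in 3 libraries, planned as stricter, kept 7735 genes and gave 695 and 2037 higher in knockouts, 975 lower and 53 higher between regions, and Cyp11a1 at 0.19. Fits of 6 libraries, with fewer libraries, gave 112 higher and 553 lower in Leydig-targeted knockouts, 224 lower between regions in wild type and 152 higher in knockouts. Those fits kept genes that passed the filter over all 12 libraries. With the filter repeated on the 6 Leydig-targeted libraries, 418 genes were tested, with 90 higher and 83 lower in knockouts.

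The replicate block gave 9 interactions and a section cell cycle p of 0.0462 and changed no other count by over 1.5 times and no other list call. Named genes lost 8 calls, none in the genotype comparison of sections: Trp53inp1 in Leydig-targeted libraries, Aurka, Fdft1, Id4 and Igfbp7 between regions in wild type, mt-Cytb and Fdxr in knockouts, and Mea1 for the interaction. Over 6 section libraries alone it gave 1870 higher, against 1749 in those libraries without the block. Outside sections the numbers did not pair the libraries, with correlations of -0.00357, 0.00818 and -0.00629 between genotypes in Leydig-targeted libraries. With an estimated correlation the steroidogenesis, Leydig identity, cholesterol, cell cycle and oxidative stress lists had adjusted p = 0.277 in Leydig-targeted libraries, and in sections 0.165, 0.165 and 0.168 for the first 3 and 0.187 for oxidative stress. By fry the section p was 0.00622 for cell cycle, and heat shock (0.701) and endoplasmic reticulum stress (0.661) pointed down. TMM for sparse libraries gave 364 and 376 lower between regions and 38 interactions. Without both shallow libraries 413 were lower between regions in wild type, the Leydig-targeted cell cycle p was 0.0522, section endoplasmic reticulum stress turned (0.923) and Cyp11a1 was at 0.10.

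Scaling to steroidogenesis and Leydig identity counts shifted the median log2 fold change by -1.62 and -2.27 in the genotype comparisons of Leydig-targeted libraries and sections and by -1.22 and -0.57 between regions in wild type and knockouts. A shift of all genes turns any smaller fold, so the turns below say nothing of single genes. It gave 30 higher and 2307 lower in Leydig-targeted knockouts, 13 and 4091 in sections, 65 and 2867 between regions in wild type and 34 and 515 in knockouts. The Leydig-targeted cell cycle p was 0.0584, and Leydig-targeted heat shock (0.795) and section endoplasmic reticulum stress (0.910) turned. In Leydig-targeted libraries Tpm1 (-0.15), Clu (-0.56), Sparc (-0.20), Star (-0.71) and Cyp17a1 (-0.076) turned. In sections Pdgfra (-0.11), Klf6 (-0.35), mt-Atp6 (-1.38), Ndufa4 (-0.48), Cox7b (-0.39), Tpm1 (-0.45), Mylk (-0.82), Hbb-bs (-0.96), Defb36 (-0.065), Nr2f2 (-0.22), Star (-0.027) and Cyp17a1 (-0.68) turned. List medians then below 0 in sections included Sertoli (-0.94), oxidative stress (-0.997), cholesterol (-0.28) and steroidogenesis (-0.38). Library size alone shifted medians by 0.20, 0.57, 0.57 and 0.19, TMM over genes not lower in knockout sections by -0.27, -0.54, -0.13 and 0.14, TMM for sparse libraries by -0.16, 0.31, 0.25 and -0.22, and DESeq2's size factors by 0.12 between regions in wild type.

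Leaving out single libraries gave 69 to 428 higher and 523 to 1273 lower in Leydig-targeted knockouts, 914 to 1588 and 1742 to 2046 in sections, 105 to 242 and 234 to 687 between regions in wild type, 44 to 136 and 63 to 489 in knockouts, and 7 to 78 interactions. In Leydig-targeted libraries list p ran from 0.00317 to 0.123 for steroidogenesis, 0.00317 to 0.0614 for Leydig identity, 0.582 to 0.983 for heat shock, 0.393 to 0.961 for endoplasmic reticulum stress and 0.0187 to 0.0446 for cell cycle, and in sections from 0.0343 to 0.0717 for cell cycle. Heat shock turned without knockout replicate 3 (0.866) and wild-type replicate 1 (0.983), endoplasmic reticulum stress without wild-type replicate 3 (0.961), Cyp11a1 without wild-type replicates 2 (0.25) and 3 (0.09), and Igf1r (-1.13) and Hbb-bs (0.16) without knockout replicate 1. With single libraries left out Igf1r ran from -1.13 to 2.86, Hbb-bs from -7.03 to 0.16 and Cyp11a1 from -1.66 to 0.25.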

Other observations

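The tests in this part were all chosen only after the results were seen, and 4930430E12Rik was named after its values were seen. Transcripts of 4930430E12Rik were found almost only in knockout entire sections, with 490 counts there, 159 to 166 per library, against 3 in wild-type sections, 1 in wild-type and 0 in knockout Leydig-targeted libraries. That is 412 CPM (376 to 450) in knockout sections, and a count of 0 in knockout Leydig-targeted libraries allows up to 27.8 CPM by the floor of 3 counts, or 34.2 by the exact interval. Wfdc18, a secreted protein gene, had 46 to 48 counts in each knockout section library and none elsewhere.

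Medians of the Leydig identity and cholesterol synthesis lists were higher in knockouts. Apart from Leydig identity in entire sections, not every member was called, and no list call held with an estimated correlation. A lower share of germ cell RNA would raise markers of all other cell types alike if expression within those cells stayed the same. That condition was not tested. However, the median of the Leydig identity list exceeded that of the Sertoli list by 1.22 in entire sections (2.48 with quartiles 1.91 to 2.83, against 1.26 with 1.05 to 1.55; two-sided permutation p = 0.00134 over genes). In Leydig-targeted libraries it was by 1.23 (permutation p = 0.00665). In entire sections the Leydig identity difference argues against a lower germ cell share as the whole cause, if Sertoli expression was unchanged. Macrophage medians were also above the Sertoli median, at 2.24 (quartiles 1.57 to 2.89) in sections and 2.48 (1.32 to 4.47) in Leydig-targeted libraries. The rise above Sertoli genes was therefore not particular to Leydig genes. In Leydig-targeted libraries the difference cannot decide, because the share of RNA from tubules, which hold germ and Sertoli cells, may differ between genotypes. The permutation p values treat genes as replicates and do not measure the spread between libraries. The cholesterol median exceeded the Sertoli median by 1.71 in Leydig-targeted libraries, or 1.21 with absent genes at their bound (permutation p = 1.20e-04 and 0.0121). Quartiles were apart, but a difference in tubule RNA could also give this, so it does not decide the question there. In entire sections the cholesterol median was higher by 0.71 (permutation p = 0.0176), but quartiles of 0.81 to 2.44 include those of the Sertoli list. For cholesterol genes in sections a lower germ cell share therefore stays open. A larger share of Leydig cell RNA stays open. Scaled to steroidogenesis and Leydig identity counts, the cholesterol median in Leydig-targeted libraries went from 2.23 to 0.56. More Leydig RNA per area and more expression per Leydig cell remain candidate explanations.

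Wild-type Leydig-targeted libraries held spermatocyte and spermatid transcripts, and knockout ones nearly none. The wild-type ratio of spermatocyte to elongating spermatid counts was 0.270, 0.317 and 0.409 in replicates 1 to 3 (pooled 0.285), against 0.204, 0.119 and 0.125 in wild-type sections (pooled 0.145). Every Leydig-targeted library lay above every section library, also at the ends of their counting intervals (0.241 or more against 0.212 or less). Those intervals do not measure the spread between libraries, and section libraries already differed from each other beyond counting error. The higher ratio in every Leydig-targeted library argues against RNA of the whole section as the only source, although it rests on 3 libraries against 3. A difference in depth between the genotypes is argued against too. Their depths overlapped, the deepest library of each held 3.70% of 54882 counts and 0.0453% of 53003, and the lowest wild-type share, 1.63%, was 36.0 times the highest knockout share, 0.0454%. Light reaching neighbouring tubules remains a candidate explanation that was not tested.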
